A study of Drosophila melanogaster with 10 samples.

How the data were processed

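All 10 RNA-seq libraries of S2 cells were used, 2 in each of 5 groups. Per the labels' protocols, HEK293T cells were added at a fixed number per S2 cell, libraries were made from 1 ug of total RNA with a stranded poly(A) kit, and single reads of 50 bp were sequenced. Per the submitters' processing notes, STAR 2.6.1 and edgeR (version not given) were used with the builds hg38 and dm6. The steps between reads and tables are otherwise not given in the sources used here.

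The authors deposited a table of read counts per gene for each library, with counts for 17490 fly and 58336 human genes in 3 strand columns. Column 4 was used, since it held the larger total of both stranded columns in every library. The 4 summary lines that name no gene (unmapped, multimapping, no feature and ambiguous reads) were left out and took 25.1 to 27.2% of reads. The authors also deposited a table of 7836 genes with log2 FPKM per library and a log2 fold change and FDR, a p-value adjusted for multiple tests, per dsRNA. Its FPKM values equal the counts used here up to a factor per library and per gene for 99.9% of values, within 0.01 on the log2 scale. Symbols came from the name tables for 17383 fly gene IDs, and coordinates from an Ensembl annotation of dm6 that held 98.0% of tested genes. The 8 list members without a match were not analysed here.

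Fly counts were analysed in R 4.3.3 with edgeR 4.0.16. One model held the 5 groups, with TMM scaling over fly genes, the filterByExpr filter and quasi-likelihood tests. Each target was the mean of its dsRNA groups. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over 8799 genes. The SE of a log2 fold change is its size over the square root of the F statistic. The typical biological variation between replicates was 6.58%. Human genes entered only the spike-in share and spike-in scaling. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one. All 30 lists, the gene classes, the rule for named genes and the alternatives not marked otherwise were fixed before the data were examined. One list, replication-dependent histones, had too few tested members.

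Named genes are dre4 and Ssrp, the 8 largest rises and 8 largest falls per knockdown among called genes with a symbol other than a CG or CR number, a mean of at least 5 CPM and all 4 knockdown libraries on one side of both controls, up to 4 called members per list with the smallest adjusted p, and for Spt16 against SSRP1 the 5 smallest adjusted p per direction. Genes picked after their values were seen are marked as such.

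Simulated counts for Spt16 against eGFP held 200 changed genes, with 8624 genes tested. In them edgeR recovered 49.0% of genes changed 1.25-fold, 75.5% at 1.5-fold, 85.7% at 2-fold and 92.0% at 4-fold, and called 8 unchanged genes. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom of 6.92 to 31.8), so none was treated as a duplicate. Counts this deep leave little counting error for most genes, and the SE and SD values given also cover variation between libraries.

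Alternatives were median-ratio size factors, spike-in scaling, total counts, DESeq2 1.42.0, other filters, unstranded counts, fewer groups in the fit, pooled dsRNAs, a replicate block, each library left out, single dsRNAs, a 2-fold threshold and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Chosen after seeing the data were the fit without mitochondrially encoded genes, the overlap with the controls split, and total counts for single dsRNAs.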

Results

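Gene expression was measured by RNA-seq in Drosophila S2 cells, an embryonic, macrophage-like cell line, after RNA interference against either subunit of FACT. FACT is a histone chaperone that moves histones H2A and H2B off and onto nucleosomes during transcription and replication, and it is a complex of Spt16 (gene dre4) and SSRP1 (gene Ssrp). Cells were treated for 4 days with double-stranded RNA (dsRNA) of about 400 bp, and a dsRNA against eGFP, which S2 cells lack, served as the control. Each subunit was targeted by 2 dsRNAs, a and b, from separate parts of the mRNA. The 5 groups (eGFP control, Spt16 dsRNA a, Spt16 dsRNA b, SSRP1 dsRNA a and SSRP1 dsRNA b) had 2 libraries each, from independent cultures according to the labels. Human HEK293T cells, a kidney-derived line, had been added to the harvested fly cells as a spike-in. Fly gene counts ranged from 21459417 to 30281113 per library and human gene counts from 62026890 to 95547427. After filtering, 8799 fly genes were tested.

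The first question was whether each dsRNA lowered its own target. The dre4 mRNA (FBgn0002183, 3L, 1871574 to 1876312 in dm6) stood at 324 ± 1.1 CPM (fly counts scaled to a common library size; SD, n = 2) in eGFP libraries and at 133 ± 7.4 CPM (SD, n = 4) in the Spt16 libraries, with 39.1% of the control left with dsRNA a and 42.9% with dsRNA b. The individual Spt16 libraries lay between 126 and 141 CPM. Ssrp (FBgn0010278, 2R, 23806361 to 23809004) fell from 290 ± 4.1 CPM (SD, n = 2) to 75.2 ± 5.0 CPM (SD, n = 4) in the SSRP1 libraries, with 24.6% left with dsRNA a and 27.3% with dsRNA b. The log2 fold change was -1.35 for dre4 with dsRNA a and -1.22 with dsRNA b, and for Ssrp it was -2.02 with dsRNA a and -1.88 with dsRNA b (edgeR quasi-likelihood test, adjusted p of 2.88e-11 or less in all 4). The mRNA of the partner subunit rose in each knockdown. Ssrp was higher in Spt16 knockdown by 0.52 on the log2 scale (SE 0.0563, edgeR adjusted p = 5.94e-07), and dre4 was higher in SSRP1 knockdown by 0.51 (SE 0.0569, edgeR adjusted p = 4.32e-07).

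**Figure D1:**
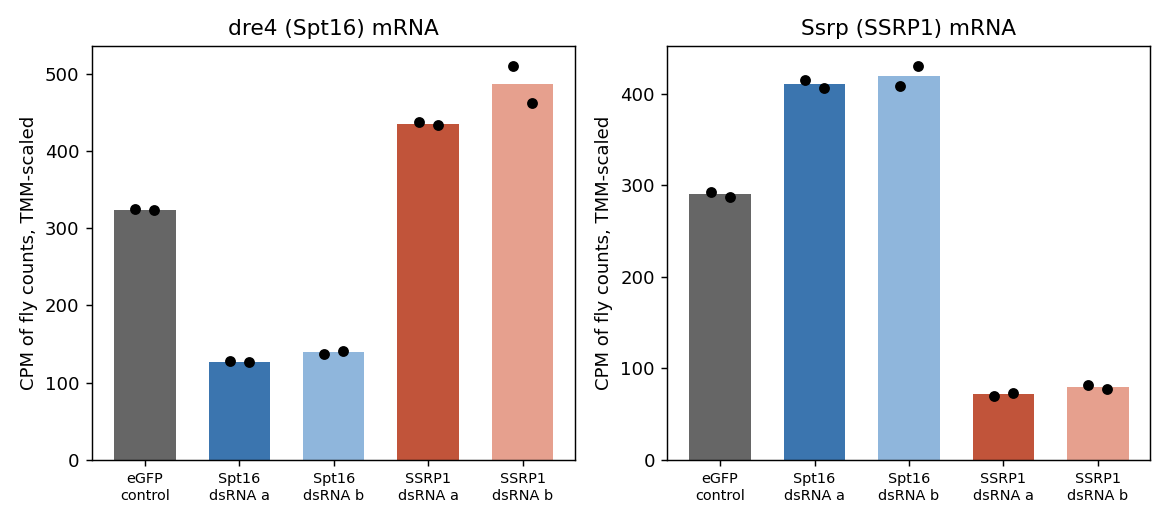
TMM-scaled CPM of dre4 (left) and Ssrp (right) in the 5 groups; bars are means and points the 2 libraries of each group. The Spt16 libraries hold 126 to 141 CPM of dre4 against 324 in the control, and the SSRP1 libraries average 75.2 CPM of Ssrp against 290.

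Spt16 knockdown against eGFP asked which transcripts depend on this subunit. Most tested members of the DNA replication and mitosis lists were called lower, and more members of the apoptosis and DNA damage, JAK-STAT and EGFR feedback lists were called higher than lower. These lists were called at a preset correlation and not with an estimated correlation (adjusted p = 0.245 to 0.494 with an estimated correlation). In all, 2622 of 8799 genes passed an adjusted p of 0.05 in edgeR, 1319 higher and 1303 lower. Changes of at least 2-fold were mostly rises, with 388 genes higher and 52 lower.

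Among the named genes with a mean of at least 5 CPM, EbpIII (FBgn0011695, 2R, 24026172 to 24027518) rose most in Spt16 knockdown. It went from 0.265 ± 0.082 CPM (SD, n = 2) to 7.22 ± 1.4 CPM (SD, n = 4), a log2 fold change of 4.75 (SE 0.285, edgeR adjusted p = 1.18e-10). The serine protease gene Ser7 rose by 3.25 and the tetraspanin gene Tsp42Ed by 2.68, the latter from 53.3 to 342 CPM. GstD5 (a glutathione transferase) rose by 2.34, CARPB by 2.32, Swim by 2.23, Tep2 (a thioester-containing protein) by 2.22 and Tig (the matrix protein tiggrin) by 2.21. The largest falls were those of the growth factor gene Pvf1 (log2 fold change -1.76), the cytochrome P450 gene Cyp12a5 (-1.67), NT5E-2 (-1.62) and the chloride channel gene ClC-a (-1.39). Each was larger than the fall of dre4 itself with either dsRNA. Further down, hdly changed by -1.23, sli, which encodes the Slit guidance ligand, by -1.22, and the mannosidase gene LManI by -1.18.

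Among the fixed gene lists, DNA replication had 29 of 41 tested members lower in Spt16 knockdown and 0 higher (33 lower when adjusted over the list alone; adjusted p = 0.278 with an estimated correlation). The helicase subunit genes Mcm7 and Mcm6 changed by -0.77 and -0.58 on the log2 scale, the licensing factor gene dup by -0.73 and the chromatin assembly gene Caf1-180 by -0.51. For mitosis, 23 of 33 members were lower and 1 higher (24 and 1 adjusted over the list alone; adjusted p = 0.245 with an estimated correlation). Examples were CycB (-0.71), the chromosomal passenger genes borr (-0.63) and aurB (-0.46), and scra (-0.52), which encodes anillin. The cytosolic ribosomal protein list had 54 of 86 members lower and 1 higher (59 and 1 adjusted over the list alone; adjusted p = 0.494 with an estimated correlation). RpS5a changed by -0.48 and RpL7A by -0.44. With dsRNA a alone this list was no longer called (camera adjusted p = 0.673). In the heat shock list 8 of 14 members were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.494 with an estimated correlation), with Hsp26 at -1.17, Hsp68 at -0.96 and the noncoding lncRNA:Hsromega at 0.65. That call was lost with dsRNA b alone (camera adjusted p = 0.177).

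The apoptosis and DNA damage list had 13 of 22 members higher and 2 lower in Spt16 knockdown (13 and 3 adjusted over the list alone; adjusted p = 0.494 with an estimated correlation). The cell death gene rpr (FBgn0011706, 3L, 18397535 to 18398435) rose from 100 ± 3.7 CPM (SD, n = 2) to 217 ± 8.0 CPM (SD, n = 4), a log2 fold change of 1.11 (SE 0.0604, edgeR adjusted p = 2.23e-11). Gadd45 rose by 1.07 and the end-joining gene Ku80 by 0.62, whereas egr, the fly tumour necrosis factor, changed by -0.91. The JAK-STAT list had 4 of 9 members higher and 0 lower (4 and 1 adjusted over the list alone; adjusted p = 0.278 with an estimated correlation), led by Tep2, the feedback inhibitor gene Socs36E (1.35) and the cytokine genes upd3 (1.54) and upd2 (1.07). In the EGFR-Ras-MAPK feedback list 7 of 11 members were higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.467 with an estimated correlation). The EGFR inhibitor gene kek1 rose by 1.48, edl by 0.97, aop by 0.44 and sty, which encodes Sprouty, by 0.43.

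These 7 lists were called by camera with a preset correlation of 0.01, among 29 lists tested. Camera adjusted p values were 7.95e-14 for ribosomal proteins, 4.93e-11 for DNA replication, 8.79e-10 for mitosis, 0.00138 for EGFR feedback, 0.00517 for apoptosis and DNA damage and 0.00608 for both JAK-STAT and heat shock. None held with an estimated correlation, the lowest adjusted p then being 0.245, for mitosis. The gene count fell to 1728 without eGFP replicate 1, to 1528 without eGFP replicate 2, and to 1579 with both dsRNAs of a target pooled as one group. Under human spike-in scaling it was 1673, 677 higher and 996 lower (40.5% higher against 50.3%), and with total fly counts it was 2496, of which 64.3% were higher.

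SSRP1 knockdown against eGFP also had most tested members of the DNA replication and mitosis lists called lower, and more members of the apoptosis, JAK-STAT and EGFR feedback lists called higher than lower. None of these list calls held with an estimated correlation (adjusted p = 0.187 to 0.428 with an estimated correlation), and the last 3 were also lost with dsRNA a alone or under spike-in scaling. Here 3896 of 8799 genes passed an adjusted p of 0.05 in edgeR, 1889 higher and 2007 lower, and 647 rose and 194 fell at least 2-fold. EbpIII again showed the largest rise among the named genes with at least 5 CPM, to 13.0 ± 7.9 CPM (SD, n = 4) and a log2 fold change of 5.38 (SE 0.275, edgeR adjusted p = 4.5e-12). The integrin alpha gene ItgaPS5 (FBgn0034880, 2R, 23556672 to 23560263) went from 2.71 ± 0.016 CPM (SD, n = 2) to 66.0 ± 9.5 CPM (SD, n = 4), a log2 fold change of 4.60 (SE 0.145, edgeR adjusted p = 3.46e-15). Other large rises were those of obst-J (3.67), the odorant receptor gene Or22a (3.19), Sp212 (3.18), Swim (3.11), bab1 (2.90), which encodes a transcription factor, and Tsp42Ed (2.84). The largest falls after Pvf1 (-2.92) were NT5E-2 (-2.32), Cyp12a5 (-2.19), CREG (-2.15), Ssrp itself, Ugt317A1 (-1.88), Pura (-1.83) and the gap junction gene Inx3 (-1.78).

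In SSRP1 knockdown 33 of 41 DNA replication genes were lower and 1 higher (34 and 1 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation). Mcm7 changed by -0.87, Mcm6 by -0.76, the ribonucleotide reductase gene RnrS by -0.60 and geminin by -0.53. Of 33 mitosis genes, 26 were lower and 1 higher (the same counts adjusted over the list alone; adjusted p = 0.187 with an estimated correlation), with CycB at -1.14, Top2 at -0.79, scra at -0.68 and aurB at -0.66. The ribosomal protein list had 39 of 86 members lower and 1 higher (41 and 2 adjusted over the list alone; adjusted p = 0.604 with an estimated correlation). RpL32 showed the largest change among its named members, at -1.05, and varied widely between the SSRP1 libraries (2195 ± 1150 CPM, SD, n = 4). This SD spans both SSRP1 dsRNAs and so can hold a difference between them. RpS5a was at -0.56 and RpL7A at -0.53.

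The apoptosis and DNA damage list had 13 of 22 members higher and 4 lower (13 and 5 adjusted over the list alone; adjusted p = 0.428 with an estimated correlation). Its member rpr rose by 1.41, p53 by 1.01 and Ku80 by 0.79, while the checkpoint kinase gene lok changed by -1.08. The JAK-STAT list had 7 of 9 members higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.352 with an estimated correlation), with Tep2 at 1.99, upd3 at 1.79, Socs36E at 1.28 and Stat92E at 0.30. In the EGFR-Ras-MAPK feedback list 7 of 11 members were higher and 1 lower (7 and 2 adjusted over the list alone; adjusted p = 0.428 with an estimated correlation). There kek1 rose by 1.48 and edl by 0.85, and ed changed by -0.80. The ribosome biogenesis list had 19 of 29 members higher and 2 lower (20 and 2 adjusted over the list alone; adjusted p = 0.401 with an estimated correlation), among them mod (0.50), eIF6 (0.47) and Polr1A (0.35), the largest subunit of RNA polymerase I. The lamellocyte marker list is named for a flat blood cell type that encapsulates parasites. Of its 9 tested members, 5 were higher and 1 lower (the same counts adjusted over the list alone, and camera adjusted p = 0.428 with an estimated correlation). Tep4 rose by 2.23, Itgbn by 2.05, mys by 0.83 and rhea by 0.55. Whether these members mark that cell type in S2 cells was not tested.

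Camera with the preset correlation called these 8 lists, with adjusted p of 1.25e-10 for mitosis, 1.21e-09 for DNA replication, 5.89e-06 for ribosomal proteins, 0.00246 for ribosome biogenesis, 0.00697 for JAK-STAT and 0.0145 for each of apoptosis, EGFR feedback and lamellocyte markers. None held with an estimated correlation (lowest adjusted p = 0.187, for mitosis). With dsRNA a alone the calls for JAK-STAT and EGFR feedback (adjusted p = 0.0896 for both) and lamellocyte markers (0.123) were lost, and under spike-in scaling those for ribosome biogenesis (0.21) and apoptosis (0.106). The gene count fell to 2943 with both dsRNAs of a target pooled as one group, and it also fell with either eGFP library left out. Spike-in scaling left 3771 genes called, but 953 were then higher and 2818 lower, 25.3% higher against 48.5%. It moved the median of all genes to -0.21 on the log2 scale, from -0.013 with TMM.

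**Figure D2:**
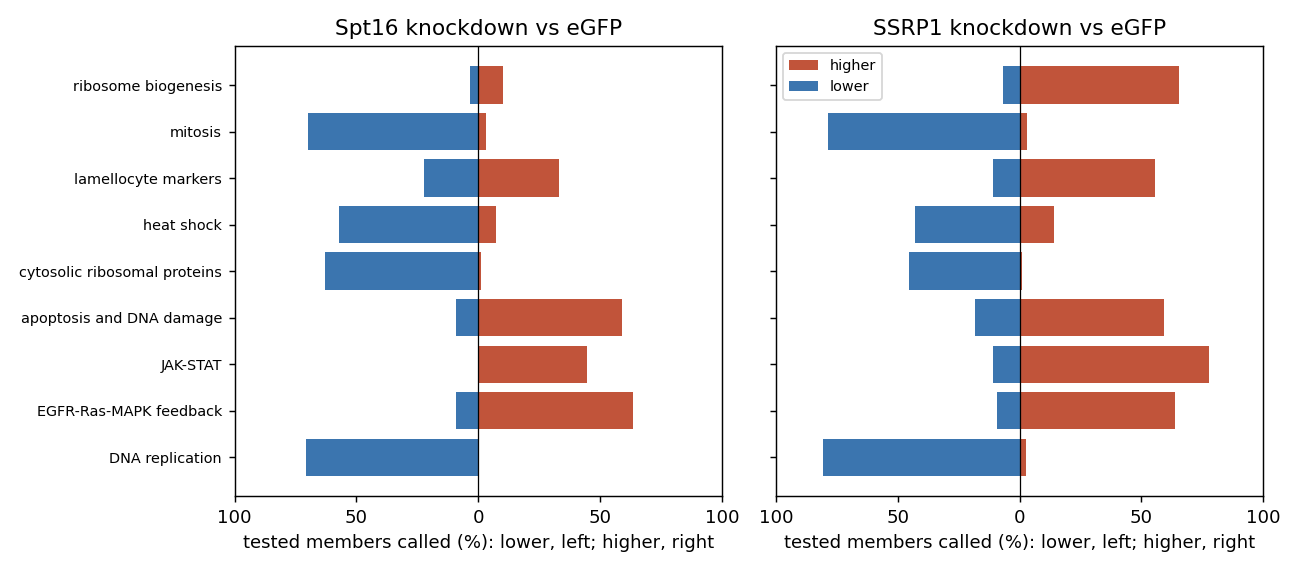
Percent of tested members called higher (right, red) or lower (left, blue) in Spt16 knockdown (left panel) and SSRP1 knockdown (right panel), for each list called in at least one of them. DNA replication has 29 and 33 of 41 members lower, and apoptosis and DNA damage 13 of 22 higher in both.

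The shared part of both responses was large. In both knockdowns 1125 genes were higher and 1097 lower, against 283 and 297 for independent lists of these sizes, and 9 genes moved in opposite directions. Both comparisons use the same 2 eGFP libraries. In 20 simulations of unchanged groups against shared controls, at most 1 gene was called in both in either direction. With no gene changed, few calls could be made. These simulations therefore do not show how shared controls add to the overlap among changed genes. The log2 fold changes correlated across genes, which are not independent replicates, at 0.87 (0.66 simulated), and their covariance was 0.47 against 0.064 simulated. With the controls split, an alternative chosen after seeing the data, 653 genes were higher and 571 lower in both knockdowns when Spt16 was set against eGFP replicate 1 and SSRP1 against eGFP replicate 2 (124 and 118 for independent lists), and 694 and 580 the other way round (130 and 131). The covariance was then 0.49 and 0.51 and the correlation 0.51 and 0.53, over 9149 genes. Each knockdown was then set against a single control library. The overlap, 2222 genes with shared controls, was 1335 without eGFP replicate 2.

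**Figure D3:**
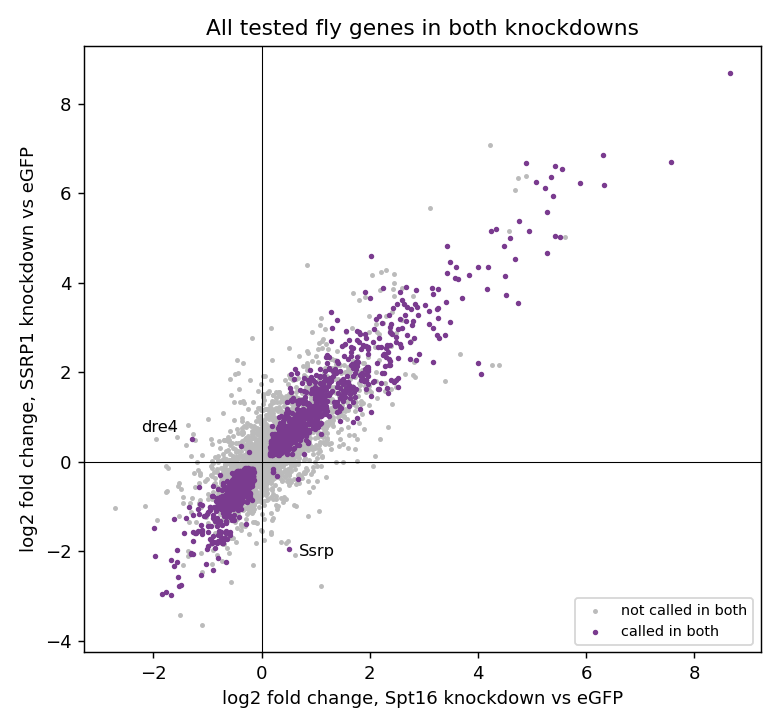
Log2 fold change of each of the 8799 tested fly genes in Spt16 knockdown (x) and SSRP1 knockdown (y), with genes called in both in purple. Most purple points lie in the upper right (1125 genes) and lower left (1097 genes), and dre4 and Ssrp lie in opposite quadrants.

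The direct comparison of Spt16 with SSRP1 knockdown tested whether both knockdowns had the same effect. It cannot tell the subunit apart from the dsRNAs used or from how far each mRNA was lowered. Spt16 dsRNAs left 39.1 and 42.9% of their target mRNA and SSRP1 dsRNAs 24.6 and 27.3%. The p-values rest on the spread between replicates of one dsRNA, not between dsRNAs. The comparison called 1872 genes in edgeR, 989 higher and 883 lower in Spt16 than in SSRP1 knockdown. Apart from Ssrp and dre4, the genes with the smallest adjusted p included ItgaPS5 (log2 difference -2.58, SE 0.0892, edgeR adjusted p = 4.78e-14), obst-J (-1.68), CG44774 (-1.10) and Esp (-1.40), all lower in Spt16 knockdown. CG1827 (1.59), CG8157 (1.79), CG15083 (0.76) and RpL32 (0.67) were higher in Spt16 knockdown. However, RpL32 varied widely between the SSRP1 libraries, which span both SSRP1 dsRNAs. CG8157 stood at 2.59 CPM in eGFP libraries, 41.7 ± 5.2 CPM in Spt16 libraries and 12.8 ± 5.0 CPM in SSRP1 libraries (SD, n = 4 for both). Of the lists, mitosis was higher in Spt16 than in SSRP1 knockdown (17 of 33 members, camera adjusted p = 1.28e-05), as were glycolysis (7 of 14, 0.00832) and replacement histones (3 of 5, 0.00944), with 0 members lower in each. None of the 3 held (adjusted p = 0.228 with an estimated correlation for each). Ribosome biogenesis (12 of 29 lower, 0.000341) and lamellocyte markers (6 of 9 lower, 0.000625) were lower, with 0 members higher, and were also lost (adjusted p = 0.273 with an estimated correlation for both). Adjusted over the list alone, 18, 7 and 4 members were higher in the first lists, and 14 and 6 lower in the last, with 1 ribosome biogenesis gene higher. The count moved to 885 with both dsRNAs pooled, to 1210 with dsRNA a alone, and to 1195 under spike-in scaling, of which 75.4% were higher against 52.8%.

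Each dsRNA was also compared with eGFP alone. Spt16 dsRNA a called 2108 genes and dsRNA b 2315, of which 851 rose and 649 fell with both. SSRP1 dsRNA a called 3077 genes and dsRNA b 3887, of which 1205 rose and 1139 fell with both. All 4 dsRNAs raised 699 genes and lowered 530. Left-out libraries moved the count for Spt16 dsRNA a to 1389 and 1374 without eGFP replicate 1 or 2 and to 1306 without its own replicate 1, and that for dsRNA b to 1452 without eGFP replicate 2. Spike-in scaling gave 1678 calls for Spt16 dsRNA a (27.1% higher against 53.8% with TMM), 1134 for Spt16 dsRNA b (60.7% against 51.3%), 1716 for SSRP1 dsRNA a (57.5% against 49.1%) and 5204 for SSRP1 dsRNA b (14.7% against 49.3%). With total fly counts the percent higher was 36.5 for Spt16 dsRNA a, 84.6 for Spt16 dsRNA b and 62.4 for SSRP1 dsRNA a. Calls in opposite directions numbered 5 for Spt16 and 15 for SSRP1. A direct test of dsRNA a against dsRNA b called 243 genes for Spt16 (179 higher with a) and 1200 for SSRP1 (560 higher with a). These last counts depended on single libraries: 129 without replicate 1 of Spt16 dsRNA a, 335 without replicate 1 of SSRP1 dsRNA a and 435 without replicate 2 of SSRP1 dsRNA b. Their direction depended on the scaling. Under spike-in scaling 16 genes were higher and 71 lower with a for Spt16, and 4452 higher and 101 lower for SSRP1, as the median of all genes moved to -0.19 and 0.42 on the log2 scale. With total fly counts 87 were higher and 3495 lower for Spt16 (median -0.25), and 1195 higher and 441 lower for SSRP1. The authors' deposited table lists 284, 290, 540 and 729 genes below an FDR of 0.05 for Spt16 a, Spt16 b, SSRP1 a and SSRP1 b, and each of these was called here in the same direction. The smallest absolute log2 fold change among the genes below that FDR in the authors' deposited table was 0.77, 0.77, 0.74 and 0.75, while calls here had no minimum fold, so the counts are not of the same kind.

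Broad gene classes showed no call in either main comparison. X-linked genes had a median log2 fold change of -0.00018 in Spt16 knockdown and -0.022 in SSRP1 knockdown (camera adjusted p = 0.788 and 0.97). Genes with a single exon, the longest 25% and the shortest 25% of genes by span had adjusted p of 0.433 or more in both. Between SSRP1 dsRNAs a and b, the longest genes were lower with a (median log2 difference -0.14, camera adjusted p = 6.29e-11) and the shortest higher (0.11, 4.16e-06), and between Spt16 dsRNAs the shortest were higher with a (0.037, 0.00725). With an estimated correlation the adjusted p were 0.137, 0.137 and 0.347.

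Human counts per fly count report on fly RNA per cell and on how many cells of each kind were mixed. The human share of counts was 72.8 ± 0.051% in eGFP libraries (SD, n = 2), 74.8 ± 1.8% in Spt16 libraries (SD, n = 4) and 75.8 ± 3.0% in SSRP1 libraries (SD, n = 4). It was above both eGFP libraries in 4 of 4 Spt16 libraries and in 3 of 4 SSRP1 libraries. The mean share exceeded that of eGFP by 1.99 points for Spt16 and 3.03 points for SSRP1. With 1 library left out, this difference ranged from 1.325 to 2.626 points for Spt16 and from 2.103 to 4.245 points for SSRP1. Exact permutation tests gave two-sided p = 0.133 for Spt16 and 0.267 for SSRP1, and with 15 regroupings the smallest p possible is 0.0667, so this test cannot pass 0.05. SSRP1 dsRNA b had the highest mean share, 78.2%, and SSRP1 dsRNA a a mean of 73.4%.

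**Figure D4:**
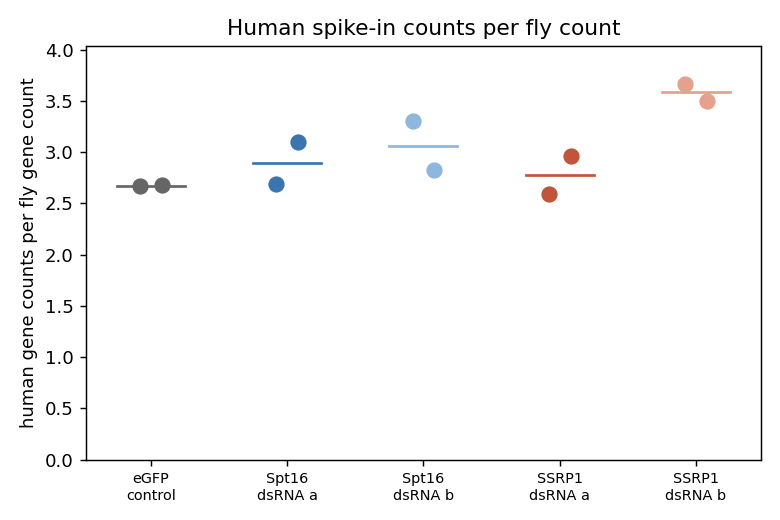
Human gene counts per fly gene count in each library (points) with group means (lines). Both eGFP libraries lie at 2.67 and 2.68, and the SSRP1 dsRNA b libraries at 3.67 and 3.50.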

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

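The test of target depletion, the fit without mitochondrially encoded genes and total fly counts for dsRNA a against b were chosen after the results were seen. If the 4 libraries of a target were alike, 18 of 360 comparisons would have 1 library apart from the rest by chance. They come from 2 dsRNAs, and a difference between these makes a single library apart rarer, so 18 is no fair bound. Over the named genes and the human share, 10 of the 360 comparisons had 1 library apart from the rest. In Spt16 libraries these were piwi at 0.914 CPM in replicate 2 of dsRNA b, and Tep4 at 658 CPM and Ppn at 10.6 CPM in replicate 1 of dsRNA a. In SSRP1 libraries they were sli at 21.2 CPM, Tep4 at 894.6 CPM and CG44774 at 1368 CPM in replicate 1 of dsRNA b, CycB3 at 28.0 CPM in replicate 2 of dsRNA b, cact at 91.1 CPM and spt4 at 53.5 CPM in replicate 1 of dsRNA a, and MsrA at 78.2 CPM in replicate 2 of dsRNA a.

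Gene lists differed between both dsRNAs of one target, by camera with the preset correlation on dsRNA a minus b. For Spt16 the median log2 differences were 0.38 for cytosolic ribosomal proteins, 0.13 for glycolysis, 0.12 for the respiratory chain, 0.097 for ribosome biogenesis, 0.084 for EGFR feedback and -0.33 for heat shock. For SSRP1 they were 0.23 for DNA replication, 0.19 for mitosis, 0.15 for the respiratory chain, -0.22 for the ecdysone response, -0.23 for EGFR feedback, -0.32 for JAK-STAT and -0.37 for lamellocyte markers. None held with an estimated correlation (lowest adjusted p of 0.181 for Spt16 and 0.237 for SSRP1). Other scalings shift the log2 fold changes of all genes nearly alike. They can so change the sign of a small median while its distance to the median of other genes stays about the same. Camera calls can still change, as those for ribosome biogenesis and apoptosis did in SSRP1 knockdown against eGFP under spike-in scaling. For Spt16 the median of all genes moved from -0.0071 to -0.19 with spike-in scaling and -0.25 with total fly counts, and the medians of EGFR feedback, the respiratory chain, ribosome biogenesis and glycolysis turned negative with both. For SSRP1 it moved from -0.0085 to 0.42 with spike-in scaling, and the medians of JAK-STAT, EGFR feedback, the ecdysone response and lamellocyte markers turned positive.

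In the ribosomal protein list 76 of 86 members were higher with Spt16 dsRNA a than b, though the list call was lost when its correlation was estimated (adjusted p = 0.181 with an estimated correlation). The median difference does not rest on a single library, since the lowest median with 1 Spt16 library left out was 0.361 against 0.384. Mitochondrially encoded transcripts took 10.4 to 11.3% of fly counts with dsRNA a and 6.28 to 7.54% with dsRNA b. Without those genes the median was 0.389. That fit is a weak test of the counts they take, since TMM scaling already offsets most of such a shift. Other scalings moved the list along with all genes, to a median of 0.202 with spike-in scaling and 0.141 with total fly counts. An off-target effect of either dsRNA may lie behind the difference and was not tested.

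More genes were called with SSRP1 than with Spt16 knockdown. Library depth did not account for this, since with every library thinned to 21459417 fly counts the ratio of calls was 1.51 against 1.49. Deeper depletion of the target stays open. SSRP1 dsRNAs left 24.6 and 27.3% of their target mRNA and Spt16 dsRNAs 39.1 and 42.9%, but the comparison of dsRNAs within a target is no test of it: the dsRNA leaving less mRNA gave more calls in 0 of 2 targets, and the mRNA left was not called different between dsRNAs a and b (edgeR adjusted p = 0.38 and 0.162). A different role of each subunit may also contribute and was not tested.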

How the results depend on the processing

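Leaving out the mitochondrially encoded genes, splitting the controls and total fly counts for single dsRNAs were chosen after the data were seen, the other alternatives before. Of 4294 values of 179 named genes under alternatives, 4019 kept their direction and side of the threshold, 197 lost the call, 45 gained one and 33 changed direction. Under human spike-in scaling the calls were 1673 for Spt16, 1195 for Spt16 against SSRP1, 1134 for Spt16 dsRNA b, 1716 for SSRP1 dsRNA a, 87 for Spt16 dsRNA a against b and 4553 for SSRP1 dsRNA a against b; of 2622 Spt16 and 3896 SSRP1 calls, 1636 and 2955 were also called in the same direction and 0 in the other. It turned the log2 fold change in SSRP1 knockdown of His3.3A to -0.042, PyK to -0.0051, Gp93 to -0.10, mt:CoI to -0.081, mt:CoII to -0.11 and mt:CoIII to -0.16, and in Spt16 knockdown of msl-2 to -0.092, Tm1 to -0.074 and mt:srRNA to -0.069. With total fly counts Spt16 dsRNA a against b called 3582 genes. With the controls split the overlap was 1224 and 1274, each knockdown then having 1 control library. With one group per target the calls were 1579 for Spt16 and 885 for Spt16 against SSRP1, and the latter was 1210 with dsRNA a alone. Genes called and at least 2-fold changed numbered 440, 841 and 200 for Spt16, SSRP1 and their difference. Without a low count filter Spt16 dsRNA a against b called 384 genes, and msl-2 was at -0.0074 (-0.0064 with unstranded counts, where mt:ATPase8 was at 0.19). With an estimated correlation 0 lists were called for Spt16 and 0 for SSRP1, and with dsRNA a alone 5 for SSRP1. The median of a gene class minus that of other genes turned, in Spt16 knockdown, from 0.0073 to -0.0129 (no filter) and -0.00216 (dsRNA a alone) for X-linked genes and from 0.0161 to -0.00434 (no filter) and -0.00259 (dsRNA b alone) for single exon genes, and in SSRP1 knockdown with dsRNA a alone from -0.0125 to 0.0155 for single exon genes, from 0.0187 to -0.0682 for the longest genes (-0.0189 without a filter) and from -0.0334 to 0.0459 for the shortest. Except for the fold threshold, which keeps fewer genes by its construction, the cause was not tested.

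With 1 library left out, calls ranged from 1528 to 2451 for Spt16, 1306 to 1545 for Spt16 dsRNA a, 1452 to 1781 for Spt16 dsRNA b, 129 to 194 for Spt16 dsRNA a against b and 335 to 1407 for SSRP1 dsRNA a against b, and the overlap from 1335 to 2308. Log2 fold changes in Spt16 knockdown ranged from -0.092 to 0.0026 for Gapdh2, -0.14 to 0.15 for msl-2, -0.086 to 0.28 for Syt1, -0.015 to 0.049 for Tm1, -0.14 to 0.13 for can, -0.18 to 0.062 for mt:ATPase6, -0.42 to 0.0074 for mt:ND5 and -0.045 to 0.089 for mt:srRNA. In SSRP1 knockdown they ranged from -0.016 to 0.17 for mt:CoII, -0.097 to 0.16 for mt:CoIII and -0.16 to 0.024 for mt:ND1. Class medians minus those of other genes ranged from -0.00538 to 0.00675 (X-linked, Spt16), -0.00615 to 0.0335 (single exon, Spt16), -0.0369 to 0.00414 (single exon, SSRP1) and -0.0239 to 0.0378 (longest genes, SSRP1). A group left with 1 library is assumed to vary like the others. The cause was not tested.

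Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.13 to 0.13 over 10 pairs of groups. With a replicate block the calls were 2507 for Spt16, 3814 for SSRP1 and 1782 for their difference, and the 7 list calls for Spt16 and 8 for SSRP1 against eGFP were kept. The block was not run for lists of the other comparisons. At this depth 49.0% of the smallest simulated changes were recovered, so changes of that size can be missed. The simulation changed only 200 genes, while 29.8% of tested genes were called in Spt16 and 44.3% in SSRP1 knockdown. More changed genes loosen the adjusted threshold, so the simulated share does not give the share recovered in these data.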

Other observations

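Only the tests of human reads and of a single dsRNA below were chosen after the result was seen, and they replace earlier forms run on the risen genes themselves; Nepl13, Zmynd10 and the mitochondrial genes were picked after their values were seen. Other gene lists held called members without a call for the list, while of all tested genes 29.8% were called in Spt16 and 44.3% in SSRP1 knockdown. Of 9 JNK and AP-1 genes, 4 were higher and 0 lower in Spt16 knockdown and 5 higher and 2 lower in SSRP1 knockdown, among them Ets21C (log2 fold change 1.09 and 1.49), Atf3 (0.56 and 1.09), puc (0.65 and 0.68) and Mmp1 (0.46 and 0.73), while camera adjusted p were 0.0729 and 0.0535. Of 20 pausing and elongation factors, 4 and 8 were lower and 0 higher, with Nelf-E, a subunit of the pausing complex NELF, at -0.53 and -0.76 (list adjusted p = 0.159 and 0.0735). The 15 FACT and histone chaperone genes, dre4 and Ssrp included, had 2 higher and 6 lower, then 4 higher and 8 lower (0.116 and 0.167). The centromeric histone gene cid changed by -0.73 and -1.05, with replacement histones at 1 higher and 1 lower of 5, then 1 higher and 4 lower, and adjusted p of 0.813 and 0.14.

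Counts of members higher and lower in Spt16 and then in SSRP1 knockdown were 6 and 2, then 7 and 2 of 19 antimicrobial and immune genes, 3 and 2, then 5 and 6 of 17 ecdysone genes, 8 and 12, then 12 and 11 of 70 respiratory chain genes, 3 and 3, then 3 and 6 of 14 glycolysis genes, and 2 and 4, then 3 and 7 of 18 ATF4 and unfolded protein genes. They were 5 and 3, then 6 and 4 of 18 oxidative stress genes, 1 and 4 in both of 11 RNA interference genes, 1 and 0, then 0 and 2 of 8 dosage compensation genes, 1 and 2, then 2 and 2 of 9 Polycomb-regulated genes, and 4 and 6, then 6 and 6 of 17 plasmatocyte markers. For crystal cell, neuronal, muscle and germline markers they were 0 and 1 in both of 3, 1 and 0, then 2 and 0 of 7, 1 and 1 in both of 7, and 3 and 2 in both of 11, and for lipid synthesis and matrix genes 3 and 1, then 4 and 2 of 10, and 5 and 3, then 6 and 4 of 13. In Spt16 knockdown, ribosome biogenesis had 3 of 29 members higher and 1 lower, and lamellocyte markers 3 of 9 higher and 2 lower; in SSRP1 knockdown, heat shock had 2 of 14 higher and 6 lower. None of these lists was called by camera (adjusted p of 0.0535 or more).

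Genes with at most 5 counts over both eGFP libraries appeared after knockdown. Of these, 110 rose in at least one knockdown, 64 with Spt16, 100 with SSRP1 and 54 with both; genes this low could only be called as rises. Nepl13 had 0 counts in both eGFP libraries and was at least 36.2-fold higher in Spt16 and 36.8-fold higher in SSRP1 libraries, against a floor of 3 counts over the group. Zmynd10 rose from 0.0374 to 3.39 and 3.10 CPM.

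To keep selection apart from measurement, genes with at most 2 counts in one eGFP library were selected as called higher in one knockdown against it, and measured in the other knockdown against the other eGFP library. The 4 such selections held 32 to 114 genes and together 169, of which 91 were among the 110 and 78 were not, so 19 of the 110 were not covered. Human reads did not account for the pooled rise of the selected genes, since without the 5 genes with most counts it was at least 2.26-fold in every held-out library, while human counts per TMM-scaled fly count rose at most 1.40-fold. Those 5 were left out after the value with them, 2.69, had been seen. The rise was not particular to the selected genes: other near-silent genes that passed the expression filter rose 1.62- to 2.50-fold in the same libraries, and all near-silent genes without that filter 1.44- to 2.26-fold. An effect of a single dsRNA stays open for a part of the genes. Of those selected with Spt16, 90.6 and 91.1% were higher with both SSRP1 dsRNAs, and of those selected with SSRP1, 79.2 and 77.2% with both Spt16 dsRNAs, against 59.0 to 65.8% of other near-silent genes. The share beyond these others ran from 35.2 to 78.3%, and it was taken as the measure after a first bound of 50% of the genes proved lower than the share of the others. Transcription running on from an expressed neighbour could apply to a part, since 21.8% of the risen genes had one upstream on the same strand within 5 kb, but most had none. The share was 12.1% among the 7978 other annotated genes with at most 5 eGFP counts (Fisher's exact test, odds ratio 2.03, p = 0.0047). Those 7978 include genes that failed the expression filter, which every risen gene had passed. This comparison therefore cannot tell a trait of the risen genes from one of genes passing the filter. No biological explanation was tested.

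The 8 knockdown libraries were split in all 35 ways into 4 and 4. In a fit of these libraries in 2 groups, the real split into Spt16 and SSRP1 called 780 genes and the highest other split 12. As many calls came from 1 of 35 splits. This share cannot exclude chance. Splits that break up a dsRNA group put differences between the dsRNA groups into the spread, which lowers their calls. Libraries of one dsRNA belong together, and only 3 of the splits keep the dsRNA groups whole, with at most 12 genes in the others, which is too few splits for a share under 0.05. A difference between the dsRNAs used is therefore not covered.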
